A study of Homo sapiens with 8 samples.

How the data were processed

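The series measured RNA by sequencing in ARP1 and H929, a pair of human multiple myeloma cell lines. Per the labels, total RNA was extracted with Trizol, passed a RNA integrity number above 7.0, was selected for poly(A), and was sequenced as paired ends on an Illumina NovaSeq from inserts of about 300 bp. The protocol text also mentions adipose tissue, which does not match myeloma lines and was not used. The labels give 8 libraries, 1 per cell line and genotype: CHEK1 overexpression, its control, CHEK1 knockdown, and its control. The labels do not say how CHEK1 was raised or lowered, so the libraries are named by their labels.

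The authors deposited 1 table of FPKM (fragments per kilobase of transcript scaled to the library's total) per transcript in the 8 libraries. Tools named per the submitters' processing notes are Bowtie 0.12.2, HISAT2 2.0 and StringTie 1.3.0, with the mouse build mm8. The transcript identifiers are human, so mm8 cannot be the build they were counted on, and the human build used is not stated. The table calls its values means, and the number of sequencing runs behind a column is not stated. Every column was matched to 1 sample by its title. Depth in reads is not given in the sources used here, so no counting error could be worked out, and precision was judged from the spread between libraries. Summed FPKM was 631871 to 693299 per library, and 23.4% of values were exactly 0.

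Transcripts were joined to genes with GENCODE release 29 on GRCh38. Of the transcripts, 87707 were matched, and 502 were not (402 with names starting LNC_ and 100 others) and were left out. FPKM was summed per gene, giving 24351 genes, of which 19554 code for protein. Values were taken as log2 of FPKM plus 1, and genes with FPKM of at least 1 in at least 2 libraries were kept, 14905 in number. Named genes on X or Y and sex-linked levels were left out.

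All 8 libraries were fitted in limma 3.58.1 with genotype and cell line as terms (3 residual degrees of freedom, 3.7 prior degrees of freedom), with contrasts and moderated variances with a trend. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The contrasts were overexpression against its control, knockdown against its control, the difference of these effects, and the control of overexpression against the control of knockdown. Pairing came from the labels: each line holds every genotype once, so the line entered as a block. The lines served as replicates (n = 2 per genotype), so the p-values measure only the spread between these samples and reach no further than ARP1 and H929. Within a line no p-value was computed. Log2 ratios of FPKM plus 1 were given, and genes at 2-fold or more were counted beside the same count between the controls of that line.

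Lists of genes, 33 in number, were fixed before the data were examined, as were the comparisons, the tests and the first set of alternatives. The 28 lists with at least 5 tested genes were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists of a contrast, with camera at an estimated correlation and fry beside it. The other 5 held too few tested genes. In each line, the median of a list was ranked among 10000 random lists matched on size and expression. Overlaps between comparisons were set beside the product of the list sizes over the number of genes. Correlations across genes are given as descriptions.

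The rule for named genes was fixed before the data were examined. CHEK1 came first, then for overexpression and knockdown the genes past the threshold with the same sign in both lines, up to 10 per direction. Where fewer passed, places up to 10 were filled by the smaller of both lines' absolute log2 ratios among genes with mean FPKM of at least 2. For each line alone the rule took the 4 largest and the 4 smallest ratios, and for each list up to 4 members. Genes without an official symbol were left out of the ranking, and 12318 tested genes remained. A gene that the ranking took is not reported here. Called genes named by clone, the protein-coding genes ranked without short transcripts, the shared coding genes, and the gene groups that open the last part of the document were chosen after their values were seen.

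Alternatives planned before the data were examined were a pseudocount of 0.1, no filter, FPKM of at least 5, median-ratio, TPM-like and quantile scaling, no block for the line, the 4 libraries of a comparison alone, both controls pooled, no trend, robust variances, transcripts in place of genes, each library left out, a 1.5-fold threshold, and the other control of the line. Added after seeing the data were gene sums without the 1035 transcripts shorter than 300 nt, FPKM weighted by transcript length, protein-coding genes alone, and a term for line by genotype with both controls of a line pooled (2 residual degrees of freedom).

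The fit was tested on simulated data. With 100 genes shifted by log2 1 and 100 by log2 2, limma called 38.4 and 87.2 of them for overexpression (14544 genes, 5 draws, 3.4 false calls on average) and 39.8 and 88 for knockdown (14537 genes, 6.8 false calls), and 0 genes in an unchanged comparison. All shifted genes were drawn from the more highly expressed genes and were shifted in the same draw. The counts therefore do not give the power for weakly expressed genes or for fewer changed genes. A list of 25 such genes shifted by 0.5 was called by camera in 20 of 20 draws, and no unchanged list was called. Simulated genes varied independently of each other, while the real lists had estimated correlations of up to 0.705 (proteasome subunits). These draws therefore cannot show how often a list of correlated genes is called without a change. The term for line by genotype called 0 of 100 genes shifted by log2 2. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and R 4.3.3, were used.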

Results

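ARP1 and H929, a pair of human cell lines from multiple myeloma, a cancer of plasma cells, were profiled by RNA sequencing. Each line was listed in 4 genotypes: overexpression of CHEK1, the control of overexpression, knockdown of CHEK1, and the control of knockdown. Each genotype had 1 library per line, so the 8 libraries gave n = 2 per genotype, with the lines standing as replicates, and no line alone had any. Levels were FPKM, fragments per kilobase of transcript scaled to the library's total, given per transcript and summed here to 24351 genes. Read depth was not given in the sources used here. Summed FPKM ran from 631871 to 693299 per library, and 13084 to 14092 genes reached an FPKM of 1. ITGB7, an integrin subunit of myeloma cells, stood at 456 to 631 FPKM, and NSD2, a histone methyltransferase gene, at 102 to 136. Of the genes fixed as markers of other cells, GNLY alone was tested for T and NK cells, CD68 and FCER1G for myeloid cells, and COL1A1, PDGFRB, KRT8 and KRT18 for stroma and epithelium. The highest level among these was 14.2 FPKM, for GNLY in the H929 overexpression library. None of 10 erythroid genes was tested, and 1 of 15 immunoglobulin genes was in the table.

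CHEK1, which encodes the checkpoint kinase CHK1 that holds cells with damaged or unfinished DNA before mitosis, was higher in the overexpression library of both lines. The gene (ENSG00000149554) lies at 125625136 to 125676255 on the plus strand of chromosome 11 in build GRCh38. CHEK1 stood at 78.2 FPKM in the ARP1 control of overexpression and 114 with overexpression, and at 81.6 and 107 in H929. The libraries labelled knockdown held 51.6 against 61.0 in their control in ARP1, and 84.8 against 80.7 in H929, so summed CHEK1 was not lower in the H929 library labelled knockdown. Folds were 1.46 and 1.32 for overexpression and 0.85 and 1.05 for knockdown. With FPKM weighted by transcript length they were 1.29 and 1.17, and 0.97 and 0.98. Transcript CHEK1-208 went from 23.5 to 38.5 FPKM with overexpression in ARP1 and from 16.4 to 25.1 in H929, while CHEK1-204 went from 6.54 to 3.50 and from 7.56 to 5.17. CHEK1-208 stood at 2.26 FPKM in the ARP1 control of knockdown and 4.59 in the ARP1 library labelled knockdown, and at 18.5 and 21.7 in H929. Between the ARP1 controls this transcript thus differed by more than summed CHEK1 did. In the ARP1 library labelled knockdown CHEK1-209 went from 11.4 to 0, more than the whole gene did. That transcript stood at 0.0007 FPKM in the ARP1 control of overexpression, 6.17 with overexpression in ARP1, and at most 0.0044 in H929. The lower ARP1 sum thus rests on a transcript barely listed in most libraries. By limma the log2 fold change of CHEK1 was 0.47 (SE 0.20, adjusted p = 0.994) for overexpression and -0.08 (SE 0.20, adjusted p = 0.903) for knockdown, and neither reached 0.05 before adjustment. Over 15 alternative settings 0.05 was reached before adjustment in 5 for overexpression and in 0 for knockdown. The control of overexpression held more CHEK1 than the control of knockdown in ARP1 (log2 ratio 0.35), and about as much in H929 (0.02). Without the ARP1 library labelled knockdown the log2 fold change of CHEK1 in knockdown was 0.21, and without the H929 one it was -0.37. For overexpression it was 0.23 without the ARP1 overexpression library and 0.71 without the H929 one.

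**Figure D1:**
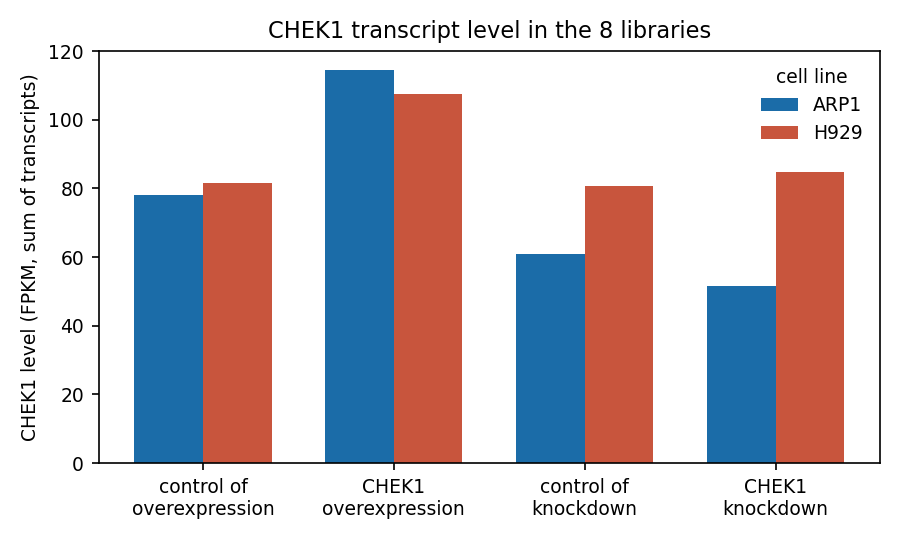
CHEK1 level (FPKM, gene sum) in each of the 8 libraries, by genotype and coloured by cell line. Overexpression libraries stood at 114 (ARP1) and 107 (H929), and the libraries labelled knockdown at 51.6 and 84.8.

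With CHEK1 overexpression, CD74 and HLA-DRA, from the list of B cell genes, were lower in both lines. CD74, the invariant chain that guides MHC class II molecules, stood at 49.5 FPKM in the ARP1 control and 14.4 with overexpression, and at 11.4 and 1.97 in H929 (log2 fold change -1.89, SE 0.23, n = 2 lines). HLA-DRA, the alpha chain of HLA-DR, stood at 159 and 69.6 in ARP1 and at 6.22 and 1.66 in H929 (-1.31, SE 0.16). HLA-DRA was also lower in the libraries labelled knockdown, with log2 ratios of -0.57 and -0.85. SREBF1, the master regulator of fatty acid synthesis, was higher, 22.6 to 58.1 in ARP1 and 29.6 to 92.5 in H929 (1.47, SE 0.21), while the other control of each line held 38.6 and 61.9. GPRC5D, a surface receptor of plasma cells, was higher at 90.4 to 296 and 63.3 to 164 (1.53, SE 0.63). None of these passed over all genes: limma gave adjusted p = 0.357 for CD74 and HLA-DRA, 0.501 for SREBF1 and 0.994 for GPRC5D.

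Other genes named by the fixed ranking as higher with overexpression in both lines, none past the test, were ABCA1, a cholesterol exporter (log2 ratios 1.23 in ARP1 and 1.99 in H929), CD52 (1.58 and 1.13), KIAA1671 (1.27 and 1.49), APOBEC3H, a cytidine deaminase (1.24 and 1.22), and SLC2A3, a glucose transporter (1.17 and 1.12). SREBF1 and ABCA1 were also higher in the libraries labelled knockdown, at 1.13 and 0.37 for SREBF1 and 1.20 and 0.94 for ABCA1. Measured against the other control of the line, ABCA1 in ARP1 (4.62 FPKM with overexpression, 5.61 in that control), SLC2A3 in ARP1 (9.67 and 10.4), APOBEC3H in H929 (3.29 and 3.40) and RN7SL36P in H929 (9.94 and 11.2) were not higher, and RN7SL284P in ARP1 was 0 in both libraries. The noncoding MINCR (-2.19 and -1.31) and ATP1B3-AS1 (-1.66 and -1.38) were lower with overexpression. The ranking also held copies related to RN7SL1 and RN7SK, such as RN7SL36P (1.59 and 1.90), RN7SL284P (-3.07 and -2.31) and RN7SKP9 (-2.11 and -3.48). Such copies may share reads with each other, which was not measured here, so their levels are uncertain. The same holds for genes that overlap another annotated gene, GPRC5D, SREBF1, ABCA1 and CD52 among them, since the strand of the reads is not stated.

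Of 14905 genes, limma with Benjamini-Hochberg adjustment called 1 in the overexpression contrast: a copy of RF02271, a short structured RNA, fell from 148 FPKM to 0 in ARP1 and from 118 to 0 in H929 (log2 fold change -7.06, SE 0.21, adjusted p = 0.000151). Its level was also 0 in all 4 libraries of the knockdown arm. Unadjusted p under 0.05 was reached by 663 genes, where 745 would be reached by chance. The call was absent without transcripts under 300 nt, with protein-coding genes alone, and with both controls pooled (0 genes each). Calls numbered 2 without the ARP1 overexpression library and 3 without the H929 one.

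Genes of mitosis and spindle assembly were higher with overexpression: 33 of 34 had a positive log2 fold change in the fit over both lines, to which all such counts refer, with a median of 0.20 (0.32 in ARP1, 0.12 in H929). Against the other control of each line that median was -0.02 (0.09 in ARP1, -0.07 in H929). ECT2, which starts cleavage of the dividing cell, stood at log2 ratios of 0.56 and 0.34, BIRC5, a chromosomal passenger and survival factor, at 0.40 and 0.31, and the spindle checkpoint kinase TTK at 0.39 and 0.28. Heat shock response genes were higher at a median of 0.15 (14 of 16; 0.27 and 0.17), among them the chaperone genes CHORDC1 (0.49 and 0.63) and HSP90AA1 (0.41 and 0.47). NF-kB targets were lower in 17 of 18 members with a median of -0.33 (-0.34 in each line). Examples were the feedback inhibitors NFKBIA (-0.50 and -0.58) and TNFAIP3 (-0.57 and -0.59) and the subunit RELB (-0.53 and -0.98). B cell genes were lower in 8 of 10 at a median of -0.53 (-0.80 and -0.24), with BCL6, a repressor of the germinal centre, at -0.94 and -0.67 beside CD74 and HLA-DRA. Type I interferon response genes were lower in 14 of 19 at -0.28 (-0.27 and -0.40), with IFI6 at -1.26 and -0.77 and IRF9 at -0.42 and -0.98. Cytosolic ribosomal proteins were lower in 34 of 41 at -0.08, with RPL13A at -0.30 and -0.25, and stood at 0.04 against the other control. Against that control heat shock response stood at 0.31 and type I interferon response at -0.53.

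The camera test of limma called these 6 of 28 lists, with adjusted p = 5.91e-08 for mitosis and spindle assembly, 0.0146 for heat shock response, 8.53e-06 for NF-kB targets, 1.83e-05 for B cell genes, 0.0329 for type I interferon response and 0.0101 for cytosolic ribosomal proteins. In that order p was 0.19, 0.374, 0.0931, 0.0157, 0.19 and 0.0917 with an estimated correlation, and after adjustment 0 lists were called that way. Adjusted over the list alone, 2 B cell genes passed (CD74 and HLA-DRA), and 0 of the 10 passed over all genes. NF-kB targets and B cell genes kept the call with any library left out. The call of mitosis and spindle assembly ended without the ARP1 overexpression library (median 0.05, adjusted p = 0.159), and so did that of heat shock response (0.04, adjusted p = 0.4). Heat shock response also lost it without the H929 control of overexpression (0.08, adjusted p = 0.471). Type I interferon response lost it without the ARP1 control of overexpression (-0.18, adjusted p = 0.271) or the H929 overexpression library (-0.17, adjusted p = 0.313). Cytosolic ribosomal proteins lost it without the H929 control of overexpression (adjusted p = 0.172) or overexpression library (adjusted p = 0.0529), and without the line as a block (adjusted p = 0.211). Without the ARP1 control of overexpression, and without the H929 overexpression library, 13 lists were called.

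No other list passed in the overexpression contrast. Median log2 fold changes were 0.07 for the ATR-CHK1 pathway and G2/M control (adjusted p = 0.0745), 0.03 for DNA replication (0.249), 0.07 for homologous recombination and Fanconi anaemia (0.0745) and 0.06 for centrosome and cohesin (0.163). Medians were 0.11 for MYC targets (adjusted p = 0.0745), 0.11 for ATF4 targets (0.175), 0.06 for p53 targets (0.623), -0.12 for the BCL2 family and apoptosis (0.0774), -0.14 for plasma cell genes (0.132) and -0.13 for antigen presentation class I (0.101). Adjusted p was above 0.1 for every remaining list, with medians of 0.10 for myeloma translocation and cyclin D genes, -0.17 for cytosolic DNA sensing, 0.05 for cholesterol synthesis, 0.05 for glycolysis and hypoxia, and -0.05 for immediate early genes. The smallest were -0.04 for ER chaperones and ERAD, 0.03 for proteasome subunits, 0.02 for nuclear-encoded oxidative phosphorylation, 0.02 for bone disease factors, 0.02 for ABC drug transporters, -0.02 for replication-dependent histones and 0.00 for mitochondrially encoded genes.

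**Figure D2:**
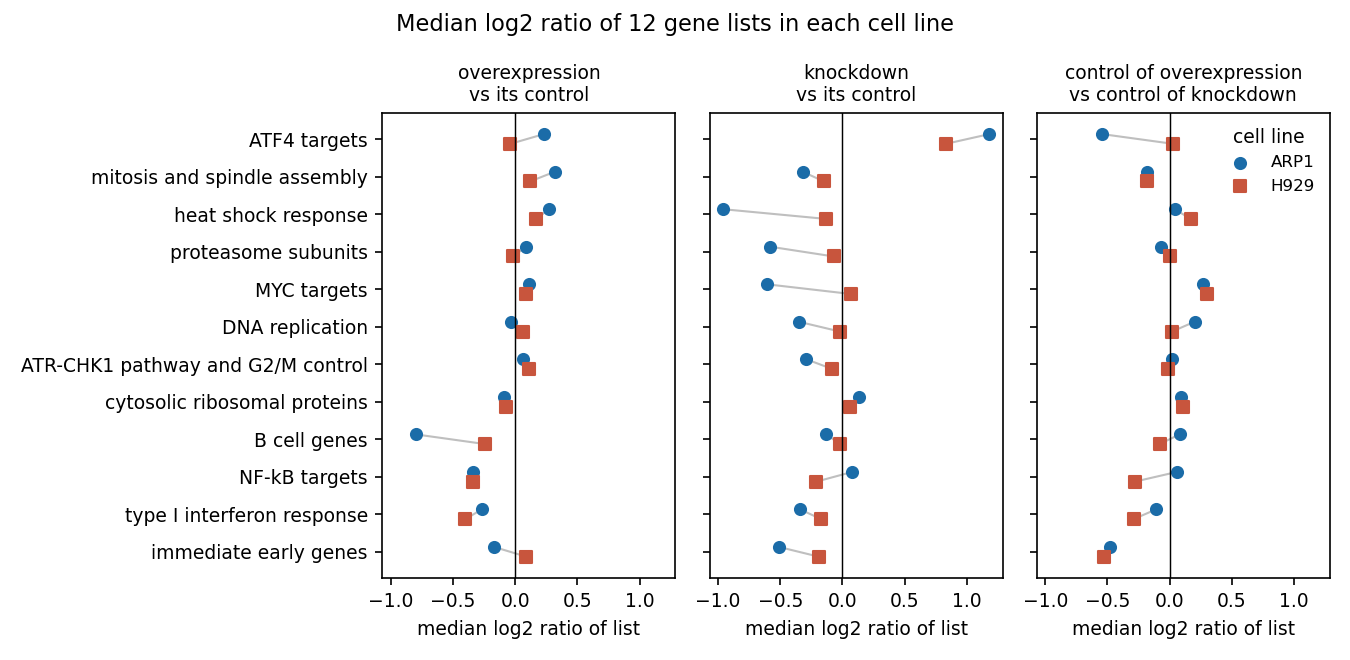
Median log2 ratio of 12 gene lists in ARP1 (circles) and H929 (squares), for overexpression, for the libraries labelled knockdown, and between the controls. ATF4 targets stood at 1.18 and 0.83 in the libraries labelled knockdown, and mitosis and spindle assembly at 0.32 and 0.12 with overexpression.

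In the libraries labelled knockdown, targets of ATF4, the transcription factor that answers amino acid shortage and protein stress, were higher in both lines. CHAC1, an enzyme that breaks down glutathione, stood at 12.4 FPKM in the ARP1 control and 63.9 in the library labelled knockdown, and at 3.59 and 19.8 in H929 (log2 fold change 2.23, SE 0.34, n = 2 lines). CTH, an enzyme of cysteine synthesis, stood at 14.6 and 53.4 in ARP1 and 9.79 and 32.0 in H929 (1.71, SE 0.48). Of 21 ATF4 targets 20 were higher in both lines, with a median log2 fold change of 0.90 (1.18 and 0.83). Other examples were STC2, a secreted glycoprotein gene (log2 ratios 2.04 and 1.37), SLC7A11, the cystine importer (log2 fold change 1.28, SE 0.31), and ASNS, asparagine synthetase (log2 ratios 1.24 and 1.18). Adjusted over the list alone, 14 of the 21 passed, TRIB3, ASNS, CHAC1, DDIT3, SLC7A11 and CTH among them, and 0 passed over all genes by limma.

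The fixed ranking also named INHBE (log2 ratios 2.79 and 1.97; 10.8 to 80.9 FPKM in ARP1), SLC6A9, a glycine transporter (2.14 and 1.82), ATF3, a stress transcription factor (1.68 and 1.79), and SESN2, an inhibitor of mTORC1 (2.26 and 1.60), all higher in the libraries labelled knockdown. LINC02100 was listed at 0 FPKM in both controls of knockdown and at 17.0 and 17.7 in the libraries labelled knockdown. The ARP1 control of overexpression held 4.15 FPKM of LINC02100 and the H929 one 0, and the gene did not pass the filter without transcripts under 300 nt. Lower in both lines were PRAME, a tumour antigen (35.2 to 14.6 FPKM in ARP1 and 3.96 to 1.48 in H929), CGN, a tight junction gene (log2 ratios -1.54 and -1.14), ZNF292 (-1.21 and -1.10), and the noncoding ATP1B3-AS1 (-1.97 and -1.31) and SEC62-AS1 (-1.94 and -1.15). ZNF292 stood at 0.34 and -0.10 without transcripts under 300 nt. Measured against the other control of the line, PRAME was not lower in H929 (1.48 FPKM, 1.05 in that control), nor ZNF292 in ARP1 (19.7 and 10.1) or H929 (16.7 and 10.1), and C7orf55-LUC7L2 was lower in ARP1 (8.19 and 20.9) and H929 (3.43 and 18.6). HMGA1P4 stood at 11.7 and 7.16 in ARP1 and at 7.77 and 4.66 in H929, and RN7SL368P at 0 in both ARP1 libraries. The antisense genes, the pseudogene HMGA1P4 (2.24 and 3.13), the read-through C7orf55-LUC7L2 (1.65 and 2.15) and the copies RN7SL569P (2.48 and 3.10) and RN7SL368P (-3.62 and -2.69) may share reads with other genes and are uncertain.

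By limma 2 genes fell in this contrast, the antisense AC010503.2 (-2.84, SE 0.21, adjusted p = 0.0304) and the sense-intronic AC025857.2 (-4.37, SE 0.28, adjusted p = 0.0244), and none rose. Both calls depend on the control. In the libraries labelled knockdown and the other control of each line AC025857.2 was 0 alike. AC010503.2 stood at 2.16 FPKM in the ARP1 library labelled knockdown and 2.47 in that control, and at 0 in both for H929. Unadjusted p under 0.05 was reached by 1362 genes, where 745 would be reached by chance. Without transcripts under 300 nt or with protein-coding genes alone 0 genes were called. Without the H929 library labelled knockdown the group held the ARP1 library alone, and log2 fold changes were 2.58 for CHAC1, 3.11 for INHBE and 2.55 for SESN2. Calls numbered 0 without either control of overexpression. Leaving out a library of this contrast left 1 library in a group, and the number of calls then fell or rose with the library. It rose most without the H929 library labelled knockdown. The ARP1 library labelled knockdown held more genes at 2-fold or more from its control than the H929 one (1231 and 536).

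Proteasome subunits were lower in the libraries labelled knockdown at a median of -0.33 (-0.58 in ARP1, -0.07 in H929): in the fit over both lines 31 of 31 were lower, and 24 were lower in ARP1 and H929 alike, with PSMA3 at log2 ratios of -1.10 and -0.45 and PSMD14 at -0.98 and -0.32. Heat shock response genes were lower in 16 of 16 in that fit, with 13 lower in ARP1 and H929 alike, at -0.54 (-0.96 and -0.13), with HSPA1B at -1.47 and -0.44 and HSPA8, the constitutive chaperone, at -1.22 and -0.35. Genes of mitosis and spindle assembly were lower in 31 of 34 at -0.22 (-0.32 and -0.15), with ANLN, a scaffold of the cleavage ring, at -0.52 and -0.50 and CEP55, which completes cell separation, at -0.52 and -0.34. The ATR-CHK1 pathway and G2/M control was lower in 21 of 27 at -0.22 (-0.29 and -0.08), with CDK1, the mitotic kinase, at -0.66 and -0.41 and TIPIN, of the replication fork, at -0.68 and -0.44. DNA replication genes were lower in 26 of 31 at -0.17 (-0.35 and -0.02), with RRM2 at -0.51 and -0.34. MYC targets were lower in 24 of 26 at -0.29, with medians of -0.61 in ARP1 and 0.07 in H929 and NME1 at -0.95 and -0.20. Cholesterol synthesis was lower in 20 of 23 at -0.22 (-0.39 and 0.04), with MSMO1 at -0.73 and -0.24. Glycolysis and hypoxia genes were lower in 18 of 25 at -0.20, with ALDOC at -0.54 and -0.91. Cytosolic ribosomal proteins were higher in 34 of 41 at 0.12, with RPS27 at 0.90 and 0.49, and stood at -0.02 against the other control of each line. Plasma cell genes were higher in 14 of 19 at 0.13, with TNFRSF17, the receptor BCMA, at a log2 fold change of 0.91 (SE 0.43) and IKZF3 at log2 ratios of 0.60 and 0.29. Against the other control plasma cell genes stood at -0.03 (0.25 in ARP1, -0.02 in H929), mitosis and spindle assembly at -0.06 (-0.16 and 0.09), ATF4 targets at 1.42, MYC targets at -0.61, cholesterol synthesis at -0.37 and DNA replication at -0.27.

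Camera called these 11 of 28 lists. Adjusted p was 9.33e-15 for ATF4 targets, 7.95e-09 for proteasome subunits, 2.12e-06 for heat shock response, 2.78e-06 for mitosis and spindle assembly, 0.000251 for MYC targets and 0.00111 for cytosolic ribosomal proteins. In that order p was 0.0936, 0.23, 0.171, 0.249, 0.348 and 0.0663 with an estimated correlation. For the ATR-CHK1 pathway and G2/M control adjusted p was 0.00751, for DNA replication 0.00906, for cholesterol synthesis 0.00906, for plasma cell genes 0.0317 and for glycolysis and hypoxia 0.0321. There p was 0.16, 0.406, 0.227, 0.185 and 0.273 with an estimated correlation, and 0 lists were called that way after adjustment. ATF4 targets, heat shock response, mitosis and spindle assembly and cytosolic ribosomal proteins kept the call with any library left out. Without the ARP1 library labelled knockdown the calls of proteasome subunits (-0.09, adjusted p = 0.0858), the ATR-CHK1 pathway and G2/M control (-0.05, adjusted p = 0.403), DNA replication (0.03, adjusted p = 0.904), MYC targets (0.04, adjusted p = 0.563), cholesterol synthesis (0.00, adjusted p = 0.563), plasma cell genes (0.09, adjusted p = 0.563) and glycolysis and hypoxia (-0.16, adjusted p = 0.0858) ended, leaving 4. Without the H929 control of knockdown adjusted p was 0.0549 for the ATR-CHK1 pathway and G2/M control, 0.0667 for DNA replication, 0.125 for plasma cell genes and 0.267 for glycolysis and hypoxia. Without the ARP1 control of knockdown it was 0.0621 for MYC targets and 0.235 for cholesterol synthesis, and without the H929 library labelled knockdown 0.0578 for glycolysis and hypoxia. Without the line as a block adjusted p was 0.0895 for cytosolic ribosomal proteins, 0.0802 for plasma cell genes and 0.125 for glycolysis and hypoxia, which stood at 0.0728 with protein-coding genes alone.

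Lists that did not pass in the libraries labelled knockdown included p53 targets, at a median of 0.08 (adjusted p = 0.197). Their member SESN2 passed adjusted over the list alone (1 of 22, 0 over all genes), BBC3, a killer protein of the BCL2 family, stood at 1.67 and 0.63, and CDKN1A, the p21 inhibitor, at -0.08 and -0.21. Medians were -0.08 for homologous recombination and Fanconi anaemia (0.667), 0.03 for centrosome and cohesin (0.374), 0.13 for replication-dependent histones (0.191), 0.01 for the BCL2 family and apoptosis (0.945), -0.02 for ER chaperones and ERAD (0.751) and -0.12 for myeloma translocation and cyclin D genes (0.645), with adjusted p in brackets. B cell genes stood at -0.12 (adjusted p = 0.937), bone disease factors at -0.03 (0.975), NF-kB targets at -0.01 (0.862), type I interferon response at -0.27 (0.124), cytosolic DNA sensing at -0.19 (0.131), nuclear-encoded oxidative phosphorylation at -0.08 (0.0924) and mitochondrially encoded genes at 0.08 (0.528). ABC drug transporters stood at -0.26 (adjusted p = 0.0805), immediate early genes at -0.21 (0.0935) and antigen presentation class I at -0.04 (0.975). Adjusted over the list alone, 4 immediate early genes passed (EGR1, ATF3, IER3 and DUSP2), and 0 over all genes.

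Within ARP1, 491 genes differed 2-fold or more with overexpression (200 higher, 291 lower) and 1231 in the library labelled knockdown (676 higher, 555 lower), beside 764 between the control libraries. In H929 the counts were 407 (191 higher, 216 lower) and 536 (275 higher, 261 lower), beside 649 between the controls. No p-value was computed within a line. Among the largest ratios by the fixed ranking were copies related to RN7SL1, such as RN7SL737P (-4.31 in ARP1 and 3.21 in H929 with overexpression), and a few coding genes. With overexpression PIP4P2 stood at a log2 ratio of 3.92 in ARP1 and SMARCA2 at 47.1 to 770 FPKM in H929, and their log2 ratios were 0.12 and 0.01 without transcripts under 300 nt. GPR157 stood at -6.03 in the ARP1 library labelled knockdown (133 to 1.04 FPKM), at -0.99 without those transcripts, and held 1.24 FPKM in the other control. SYCE1L stood at 4.74 in the H929 library labelled knockdown (0.71 to 44.8 FPKM), with 11.9 FPKM in the other control, and did not pass the filter without those transcripts.

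Protein-coding genes without short transcripts were ranked after the values were seen. With overexpression ARP1 held SPRR2A (2.37) and FGR (1.97) highest, and PTPRM (-2.32) and HEY1, a Notch target, (-2.29; 56.1 to 10.7 FPKM) lowest. H929 held ABCA1 (1.99) and FZD3 (1.84) highest, and the cytokine gene IL32 (-2.32; 26.8 to 4.57 FPKM) and MACROD2 (-2.14) lowest. In the library labelled knockdown ARP1 held FBXO27 (1.06 to 15.4 FPKM), INHBE (2.79) and TUBB3 (2.79) highest, and SPINT2 (-2.32), CFI (-2.22) and TUBB4A (-2.20) lowest. H929 held CHAC1 (2.18) highest and SYNJ2BP-COX16 (-2.27), FBXO27 (-2.10) and UTP23 (-1.81) lowest. The other control of the line held 0.60 FPKM of FBXO27 (0.92 in the H929 library labelled knockdown) and 0.39 of UTP23 (0.17), and SYNJ2BP-COX16 stood at a log2 ratio of 1.08 against it, so FBXO27 and SYNJ2BP-COX16 were not lower. In ARP1 that control held 0.46 FPKM of SPINT2 (0.55 in the library labelled knockdown), which was not lower, 1.32 of CFI (0.45) and 15.4 of TUBB4A (6.11). For overexpression it held 2.39 FPKM of SPRR2A (4.93), 2.43 of FGR (6.59) and 15.5 of HEY1 (10.7).

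Genes 2-fold apart in the same direction in both lines numbered 65 with overexpression, where independent lists would share 6.8, and 109 in the libraries labelled knockdown, where they would share 22.2. Among protein-coding genes these were 18 (0.8 by chance) and 33 (3.8 by chance). Higher in both lines with overexpression were 12 coding genes, with CD52, GPRC5D, SREBF1 and SLC2A3 among them, and lower were 6, with CD74 and HLA-DRA. Higher in both libraries labelled knockdown were 24 coding genes, with ASNS, CHAC1, SLC7A11 and STC2, and lower were 9, with CGN and PRAME. The pair of controls shared 126 such genes between the lines (17.2 by chance), and genes 2-fold apart in opposite directions numbered 47 for overexpression (6.6 by chance) and 77 for knockdown (22.1 by chance). Opposite directions thus also exceeded the chance values, which are no full yardstick for the shared counts. Across genes, which are not independent of each other, the log2 ratios of ARP1 and H929 had a Spearman correlation of 0.21 for overexpression, 0.18 for knockdown and 0.36 between the controls.

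**Figure D3:**
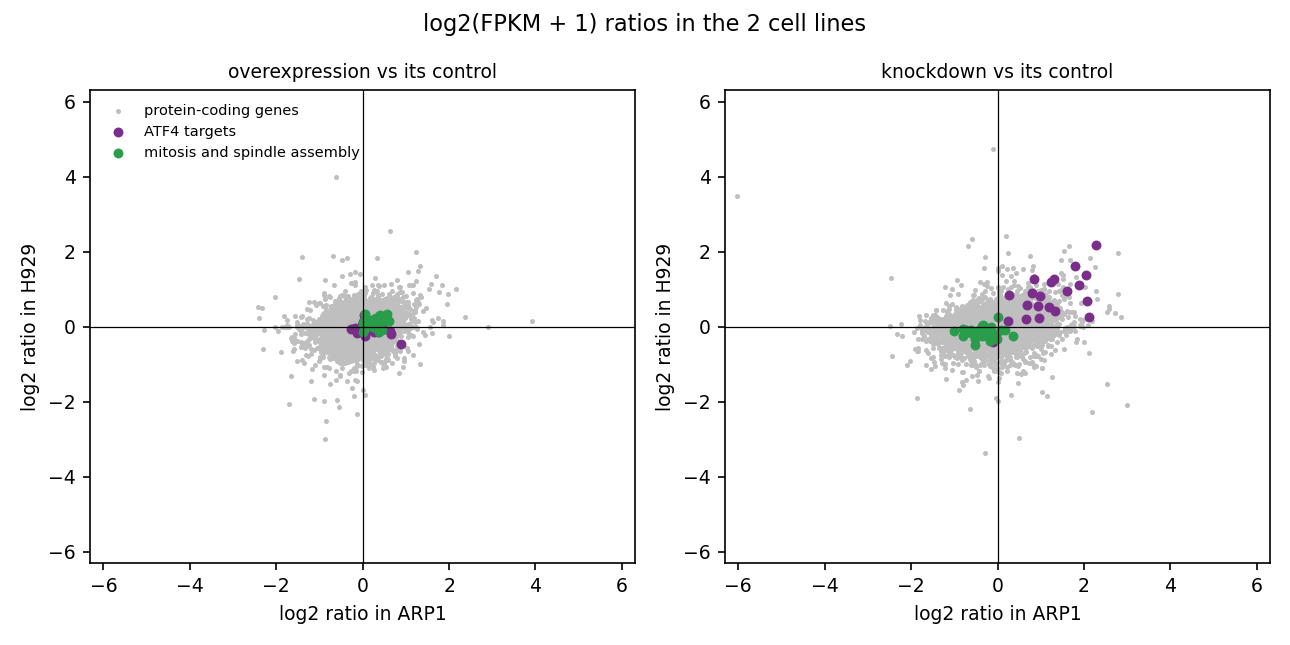
Log2 ratios of protein-coding genes (grey) in ARP1 and in H929, for overexpression and for the libraries labelled knockdown, with ATF4 targets in purple and mitosis and spindle assembly in green. CHAC1, an ATF4 target, stood at 2.28 and 2.18 in the libraries labelled knockdown.

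The overexpression effect minus the effect in the libraries labelled knockdown, each against its own control, had a median of 0.46 for mitosis and spindle assembly (33 of 34 positive) and 0.74 for heat shock response. Against the other control of each line mitosis and spindle assembly stood at -0.02 with overexpression and -0.06 in the libraries labelled knockdown, so its difference depends on the controls. The same holds for plasma cell genes (0.02 and -0.03) and cytosolic ribosomal proteins (0.04 and -0.02). Proteasome subunits stood at 0.45, MYC targets at 0.42, glycolysis and hypoxia at 0.32, cholesterol synthesis at 0.31, the ATR-CHK1 pathway and G2/M control at 0.28 and DNA replication at 0.17. ATF4 targets stood at -0.85 (20 of 21 negative), B cell genes at -0.52, NF-kB targets at -0.42, plasma cell genes at -0.30 and cytosolic ribosomal proteins at -0.19. Camera called these 13 of 28 lists, with adjusted p = 3.54e-11 for mitosis and spindle assembly, 3.36e-07 for heat shock response, 3.39e-07 for proteasome subunits, 5.62e-08 for ATF4 targets, 6.68e-05 for MYC targets and 2.53e-05 for cytosolic ribosomal proteins. In that order p was 0.139, 0.153, 0.277, 0.179, 0.323 and 0.0387 with an estimated correlation. Adjusted p was 0.00128 for the ATR-CHK1 pathway and G2/M control, 0.00463 for DNA replication, 0.0072 for cholesterol synthesis, 0.0335 for glycolysis and hypoxia, 0.00223 for B cell genes, 0.00223 for NF-kB targets and 0.0072 for plasma cell genes. There p was 0.12, 0.387, 0.229, 0.285, 0.0383, 0.198 and 0.137 with an estimated correlation, and 0 lists were called that way after adjustment. Without the ARP1 library labelled knockdown 6 lists were called, and without the line as a block glycolysis and hypoxia had adjusted p = 0.112. Adjusted over the list alone, 2 B cell genes passed (BCL6 and CD74), and 0 over all genes.

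By gene, limma called 2 in this contrast: AC025857.2 was positive at 7.27 and RF02271 negative at -7.06, and neither was called without transcripts under 300 nt. Calls numbered 0 without either control of overexpression, 5 without the ARP1 control of knockdown, and 4 without the ARP1 overexpression library or the H929 library labelled knockdown. Within ARP1, 91 genes were 2-fold apart in opposite directions with overexpression and knockdown (20.6 by chance) and 69 in the same direction (19.9 by chance). Within H929 these were 56 (7.3 by chance) and 66 (7.3 by chance). Across genes, the Spearman correlation between the overexpression and knockdown ratios was -0.11 in ARP1 and -0.01 in H929.

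The controls of overexpression and of knockdown also differed from each other. WDR74, a factor of ribosome assembly, rose to 664 and 668 FPKM in the control of overexpression from 227 and 238 in that of knockdown (log2 fold change 1.51, SE 0.12, adjusted p = 0.0165), and C7orf55-LUC7L2 (log2 ratios 2.91 and 4.29) and RF02271 (log2 fold change 7.06) rose as well. ZNF292 (-1.94, adjusted p = 0.0195), AL138963.1 (-2.59), PIGY (-1.60), AC010503.2 and AC025857.2 fell. Limma called these 8 genes, and unadjusted p under 0.05 was reached by 1600. WDR74 also stood at 575 and 525 FPKM with overexpression, and at 202 and 215 in the libraries labelled knockdown. There C7orf55-LUC7L2, AL138963.1 and ZNF292 likewise kept the direction seen between the controls, while PIGY, RF02271, AC010503.2 and AC025857.2 did not in both lines. Some differences thus lie between the arms, and a comparison with the other control of a line takes them in. Calls numbered 3 without transcripts under 300 nt, 4 with protein-coding genes alone and 2 without the line as a block. Calls numbered 1 without either control of overexpression and 1 without the H929 control of knockdown, 2 without either overexpression library, 10 without the ARP1 and 11 without the H929 library labelled knockdown.

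MYC targets were higher in the control of overexpression in 25 of 26 at a median of 0.32 (0.27 and 0.30), with NCL at 0.93 and 0.80 and NOLC1 at 0.64 and 0.87, the 2 that passed adjusted over the list alone (0 over all genes). ER chaperones and ERAD were higher in 18 of 22 at 0.33, with CRELD2 at 0.86 and 0.50 and HYOU1 at 0.89 and 0.41 (2 over the list alone, 0 over all genes). Cytosolic ribosomal proteins were higher in 29 of 41 at 0.13, with RPL38 at 1.34 and 0.80 (1 over the list alone, 0 over all genes). Immediate early genes were lower in 12 of 16 at -0.53, with FOS at -0.97 and -1.41 and EGR1 at -1.32 and -0.55. Mitosis and spindle assembly was lower in 28 of 34 at -0.18 (-0.18 in each line), type I interferon response in 16 of 19 at -0.30, and ATF4 targets in 14 of 21 at -0.22 (-0.54 and 0.03). Camera called these 7 lists, with adjusted p = 7.96e-06 for MYC targets, 4.18e-05 for ER chaperones and ERAD, 0.00169 for cytosolic ribosomal proteins, 0.000698 for immediate early genes, 0.00169 for mitosis and spindle assembly, 0.0409 for type I interferon response and 0.0409 for ATF4 targets. In that order p was 0.257, 0.0793, 0.069, 0.0398, 0.38, 0.203 and 0.501 with an estimated correlation, and after adjustment 0 lists were called that way (smallest adjusted p = 0.74). Type I interferon response lost the call without the H929 control of overexpression (-0.17, adjusted p = 0.33) or of knockdown (-0.29, adjusted p = 0.221). ATF4 targets lost it without the ARP1 control of overexpression (median 0.05) or of knockdown (-0.17, adjusted p = 0.351), and without the ARP1 (adjusted p = 0.0656) or H929 (adjusted p = 0.0653) overexpression library. Without the line as a block adjusted p was 0.0551 for cytosolic ribosomal proteins and 0.063 for type I interferon response.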

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

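The test of a difference between the lines, and every explanation tried here, were chosen after the results had been seen. Most results stand in this part for a difference between H929 and ARP1 in a term for line by genotype in limma. That fit pooled both controls of a line and had no replicate of overexpression or knockdown within a line. Its residual spread thus came only from the controls of each line. The tests of that term therefore cannot separate a difference between the lines from an odd overexpression or knockdown library. CHEK1 stands here for opposite directions of its summed FPKM in the lines, and the last 3 paragraphs weigh patterns chosen from the report. No single gene passed that test in either contrast (0 for overexpression, with 279 at unadjusted p under 0.05, and 0 for knockdown, with 1161). In simulated data the term called 0 of 100 genes shifted by log2 2, so the absence of calls cannot show that single genes did not differ.

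CHEK1 in the libraries labelled knockdown differed in direction, with a log2 ratio of -0.24 in ARP1 and 0.07 in H929, each against its own control (with FPKM weighted by length the folds were 0.97 and 0.98, in the same direction). In the fit with pooled controls, a different comparison, the lines differed by 0.48 (SE 0.28), which did not pass the test. With overexpression, mitosis and spindle assembly was lower in H929 than in ARP1 by -0.19 (adjusted p = 0.00147; p = 0.331 with an estimated correlation). NF-kB targets differed by -0.25 (adjusted p = 0.0427; p = 0.313 with an estimated correlation) with pooled controls. Against their own controls they stood at -0.34 in each line, and between the controls at 0.06 in ARP1 and -0.28 in H929. Mitochondrially encoded genes differed by 0.55 (adjusted p = 1.98e-05; p = 0.219 with an estimated correlation), and glycolysis and hypoxia by -0.26 (adjusted p = 0.0015; p = 0.102 with an estimated correlation).

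In the libraries labelled knockdown, heat shock response differed between H929 and ARP1 by 0.80 (adjusted p = 1.13e-06; p = 0.0589 with an estimated correlation). Proteasome subunits differed by 0.50 (adjusted p = 4.89e-07; p = 0.0234 with an estimated correlation) and MYC targets by 0.67 (adjusted p = 2e-06; p = 0.303 with an estimated correlation). DNA replication differed by 0.37 (adjusted p = 0.000386; p = 0.114 with an estimated correlation). Nuclear-encoded oxidative phosphorylation differed by 0.22 (adjusted p = 0.0184; p = 0.126 with an estimated correlation), and ATF4 targets by -0.75 (adjusted p = 1.21e-05; p = 0.218 with an estimated correlation).

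ATF4 targets were higher in both libraries labelled knockdown, at 1.18 in ARP1 and 0.83 in H929 against their own controls. Between the controls they stood at -0.54 in ARP1 and 0.03 in H929, so the -0.75 between the lines with pooled controls depends in part on the controls. Under every scaling and without short transcripts the median stayed at 0.90 or more, above the bound of 0.45 set for it, so these settings are unlikely to be its source. Against the other control of each line the median was 1.42 (1.79 in ARP1, 0.67 in H929), so the rise does not rest on the choice of control. That comparison crosses the arms, so it also takes in any difference between them. Whether it could follow from lower CHEK1 is open, since CHEK1 itself stood at -0.08, within 2 SE of no change. Effects of the knockdown method other than on CHEK1, and of growth conditions, were not tested.

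Genes of mitosis and spindle assembly stood higher with overexpression and lower in the libraries labelled knockdown. Against the other control of the line, the median was -0.02 for overexpression (0.09 in ARP1, -0.07 in H929) and -0.06 for knockdown (-0.16 and 0.09). Both were closer to 0 than the bounds set from the reported medians (0.10 and -0.11), so the opposite directions may come from the difference between the controls, where these genes stood at -0.18. For CHEK1 itself as the cause the test was undecided by its rule, since of the medians per line only the ARP1 knockdown one (-0.16) kept its sign and passed its bound (-0.11).

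Of the 79 genes at 8-fold or more in any comparison within a line, 84.8% fell below 8-fold without transcripts under 300 nt, above the 50% set as the bound. Most of the largest ratios therefore likely reflect transcripts about as short as, or shorter than, the inserts, for which FPKM may be unstable. The 4 comparisons of libraries labelled overexpression or knockdown with their controls held 25.25 such genes on average and the control pairs 32.5, with 9 and 15 for overexpression and 38 and 39 for knockdown, so the test for an effect of CHEK1 was undecided.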

How the results depend on the processing

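Alternatives with gene sums free of short transcripts, with FPKM weighted by length, with protein-coding genes alone, and the test of line by genotype were chosen after the results had been seen. With a pair of lines as replicates, 1 library per line and genotype and no stated read depth, small changes and weakly expressed genes could not be resolved, and a fit with a library left out assumes that the lone remaining library varies like the other groups. Among results that answer a comparison, 178 values under an alternative were the same, 100 moved and 2 reversed. Among the other named results 1992 were the same, 147 moved, 14 passed only under the alternative, 34 no longer passed and 19 reversed. CHEK1 stood at 0.29 to 0.56 for overexpression over 15 settings and at 0.23 to 0.71 with a library left out. For knockdown it stood at -0.17 to -0.02 and at -0.37 to 0.21, with 0.00 without the H929 control of knockdown. Except where a reason is given, the cause of a change was not tested.

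Genes called for overexpression numbered 1, against 2 with no filter, 0 with the controls pooled, 0 without transcripts under 300 nt, 0 with protein-coding genes alone (which removes the called gene) and 1 to 3 with a library left out. For knockdown they numbered 2, against 1 with a pseudocount of 0.1, 0 at FPKM of at least 5, 1 with TPM-like scaling, 0 without the replicate block, 0 with the controls pooled, 5 without the trend, 0 without short transcripts, 0 weighted by length, 0 with protein-coding genes alone, 1 with transcripts tested and 0 to 837 with a library left out. For the difference of the effects they numbered 2, against 1 with a pseudocount of 0.1, 0 with no filter, 0 with the controls pooled, 0 without short transcripts, 1 weighted by length, 0 with protein-coding genes alone and 0 to 5 with a library left out. Between the controls they numbered 8, against 5 with no filter, 2 without the replicate block, 3 without short transcripts, 4 with protein-coding genes alone, 33 with transcripts tested and 1 to 11 with a library left out.

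Genes at 2-fold or more with overexpression numbered 491 in ARP1 and 407 in H929. They numbered 1710 and 1331 at 1.5-fold, 1201 and 1165 with a pseudocount of 0.1, 201 and 138 at FPKM of at least 5, 826 and 892 against the other control, 206 and 90 with protein-coding genes alone, and 192 in H929 weighted by length. In the libraries labelled knockdown 1231 and 536 became 3862 and 1415 at 1.5-fold, 2160 and 1199 with a pseudocount of 0.1, 652 and 191 at FPKM of at least 5, 667 and 137 with protein-coding genes alone, and 204 in H929 weighted by length. A lower fold threshold or fewer genes tested changes such counts by construction. Genes shared between the lines numbered 65 for overexpression, against 290 at 1.5-fold, 253 with a pseudocount of 0.1, 32 at FPKM of at least 5, 201 against the other control, 39 without short transcripts, 30 weighted by length and 18 with protein-coding genes alone. For knockdown 109 became 406, 302 and 52 under the first 3 of these, 50 weighted by length and 33 with protein-coding genes alone. Genes opposite between overexpression and knockdown numbered 91 in ARP1 and 56 in H929. They became 422 and 213 at 1.5-fold, 303 and 208 with a pseudocount of 0.1, 39 and 23 at FPKM of at least 5, 181 and 182 against the other control, 53 and 31 without short transcripts, 56 and 9 weighted by length, and 22 and 6 with protein-coding genes alone.

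Lists called numbered 6 for overexpression, 11 for knockdown, 13 for the difference and 7 between the controls, and 0 in each with an estimated correlation and 0 in each with fry for a shared direction. With a library left out they numbered 6 to 13, 4 to 13 and 6 to 17 in the first 3, and without the replicate block 5, 8, 12 and 5. Fry for members moving in either direction called some lists, such as B cell genes in overexpression (adjusted p = 0.000164) and in the difference (adjusted p = 0.0329). Antigen presentation class I passed it between the controls (adjusted p = 0.0096). Median ranges with a library left out crossed 0 for DNA replication in knockdown (-0.44 to 0.03), MYC targets in knockdown (-0.56 to 0.04) and ATF4 targets between the controls (-0.55 to 0.05). ZNF292 in knockdown stood at 0.12 without short transcripts. Against the other control of the line, log2 ratios with overexpression in ARP1 were -0.13 for USP12-AS1, -0.39 for RN7SL192P, -0.51 for ASS1 and 0 for RN7SL284P, RN7SL172P and RN7SL812P. In H929 they were 0 for RN7SKP70 and RN7SL789P. For the libraries labelled knockdown they were 0.08 for SPINT2 in ARP1, and in H929 -0.24 for RN7SL809P, -0.31 for RSC1A1, -2.14 for C7orf55-LUC7L2, 1.08 for SYNJ2BP-COX16, 0.26 for FBXO27 and 0.04 for COL1A1. All settings fixed beforehand were run.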

Other observations

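Every group in this part was chosen after its values had been seen, and its rank among random lists is a description and not a test. In the ARP1 library labelled knockdown, 10 of 11 tubulin genes, which encode the building blocks of microtubules, were lower, with a median log2 ratio of -1.50 (percentile 0 among random lists). TUBA1B stood at 629 FPKM in the control and 195 in the library labelled knockdown, and TUBB at 605 and 246, while TUBB3 stood at 0.20 and 7.26. In H929 the median was -0.07 (percentile 13.4), with TUBA1B at 640 and 639. Targets of NRF2, the regulator of the response to oxidants, were lower in 10 of 12 in the ARP1 library labelled knockdown (median -0.98, percentile 0) and stood at -0.18 in H929 (percentile 0.2). Examples were PRDX1, a peroxide-removing enzyme (391 to 107 FPKM in ARP1), and NQO1 (46.9 to 12.4 in ARP1 and 48.2 to 32.1 in H929). The H929 direction rests on the choice of control, since the control of overexpression held 25.6 FPKM of NQO1 and 18.9 of HMOX1 beside 22.4 in the library labelled knockdown, and the list stood at -0.26 in ARP1 and -0.22 in H929 between the controls.

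Aminoacyl-tRNA synthetases, which load amino acids onto tRNA, were higher in 14 of 20 in each library labelled knockdown (medians 0.36 and 0.34, percentile 100 in each), with WARS at 1.32 and 0.71 and CARS at 1.08 and 1.01. RARS and TARS stood at -3.38 and -2.97 in H929, where the control of knockdown held 530 and 883 FPKM. MHC class II genes were lower with overexpression (medians -0.94 in ARP1 and -0.24 in H929, percentiles 0 and 1.5) and in the libraries labelled knockdown (-0.50 and -0.43, percentiles 0.3 and 0.1). In H929 with overexpression HLA-DPB1 (0.48) and HLA-DOB (0.12) were higher. Between the controls the group stood at -0.25 in each line, and in H929 members such as HLA-DRB1 (0.08 FPKM in the control of knockdown) and HLA-DPB1 (0.61) were barely listed, so its values in the libraries labelled knockdown depend on the control. Targets of SREBP1 and LXR, regulators of fatty acid and sterol balance, were higher with overexpression (0.47 and 0.27, percentile 100 in each), with SCD, which makes monounsaturated fatty acids, at 0.94 and 0.78 and MYLIP at 0.49 and 1.10. In the libraries labelled knockdown they stood at -0.05 in ARP1 and 0.27 in H929 (percentiles 58.9 and 100). These targets stood at -0.36 in ARP1 (percentile 0.3) and -0.02 in H929 between the controls, so their ARP1 values depend in part on the control. Between the H929 controls 6 members were lower, among them SREBF1 (-1.04), MYLIP (-0.86) and ABCA1 (-0.68), and 6 were higher, among them SCD (0.78). Values of single members in H929 thus depend on the control too.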
